A study of Arabidopsis thaliana with 12 samples.

How the data were processed

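The data were a table of linear intensity values deposited by the authors, with 3439 array features in 12 columns, 1 per sample. The scanner, background correction, image software and the quantity the intensities were divided by were not given in the sources used here. The values lay between 0 and 100, and 3 features reached 100, the top of the scale, in at least 1 column. Column means of the deposited intensities lay between 1.02 and 1.10. Column medians differed by up to 0.95 on the log2 scale and column totals by 8.17%.

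Samples were grouped by their titles and source names, per the labels, into 6 of WT and 6 of the pete1 pete2 double mutant. The labels do not say which samples came from separate plants or cultures, so the p-values measure only the spread between these samples, which may be technical. Numbers 1 and 2, 3 and 4, and 5 and 6 of each genotype differed far less than any other columns, and were averaged on the log2 scale after normalization into 3 replicates per genotype. The design fixed before the data were examined took the 12 samples as replicates unless their values agreed to rounding, and listed the averaging of such pairs as an alternative. The pair means were made the main analysis only once the agreement of the columns had been seen, before the calls were compared. The 12 columns as separate samples, the analysis planned beforehand, are given beside them.

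Because medians differed by more than 0.1 (log2) and totals by more than 1%, the columns were quantile normalized, values under the 1st percentile of the positive values (0.0225) were raised to it, and log2 was taken. A fold change against values at this floor understates the difference, and none is given for a feature listed at 0 in a whole group. Intensities are printed on the linear scale after normalization, as the mean and SD of the 3 pair values. Features were named from the platform annotation where it gave exactly 1 gene: 690 of 692 such identifiers matched the TAIR10.1 gene table, which was used for names only, and the others kept the annotation's name. No genome build is named for the array, so no coordinates are given. Features with several genes or none are referred to by number. The 1 gene with more than 1 feature was averaged, leaving 3438 tested features.

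Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all tested features and a threshold of 0.05. A permutation test of 3 against 3 cannot go below a p of 0.1, since there are 10 splits. On simulated data with the same means and spread, over 20 runs on 3438 features with 200 changed in each, the test found 10.3% of changes of 1.5-fold, 24.4% of 2-fold, 62.4% of 4-fold and 78.6% of 8-fold. It made 5.1 false calls per run and gave 0 wrong signs, and 0 calls were made over 20 runs without changes. The simulated features were independent and were not raised to the floor, and features at the floor in every column were given no spread. In the real data neighbouring features deviate together, so these rates need not hold there.

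The named genes followed a rule fixed before the data were examined: PETE1 and PETE2, the genes with the largest change past the threshold or, with fewer than 3 in a direction, the 5 named genes with the smallest p in that direction, and up to 4 members of each list with at least 4 measured members. All other measured members of the fixed lists, and features 975, 3149, 3502 and 1430, were added after the data were seen. The 25 lists held 407 nuclear genes for plastid functions, and 23 members from 12 lists were measured. A member counted as measured only where a feature was assigned to it alone. Features with several genes or none were tested but not counted, so other members may be on the array. The other 13 lists, among them light harvesting complex I, the chloroplast ATP synthase, photorespiration, carotenoids, import, chaperones, stress response, starch, jasmonate synthesis and root plastid markers, had 0 measured members. Lists with at least 4 measured members were tested with limma's camera at a preset correlation of 0.01 and with an estimated one, adjusted over 7 lists. Of these, 6 were added after the data were seen but before any fold change of a list had been computed.

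The alternatives were the values as deposited, centring on the median, scaling to the total, a pseudocount of 0.0872 (the 5th percentile of the positive values) in place of the floor, removal of the dimmest 25% or 50% of features, a trended and robust variance, array weights, a block on the replicate number, each feature on its own, stricter thresholds, leaving out each column, and the 12 columns as separate samples as planned at first. Leaving out each pair, the pair as a random block, a block on the 12 columns and a correction for neighbouring features were added after the data were seen. Correlations between features were computed by feature number. The row length of 288 was the distance from 50 to 400 at which the difference of the first WT pairs correlated best, as the array's layout was not given in the sources used here.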

Results

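Transcript levels were compared between wild-type (WT) Arabidopsis thaliana of the Columbia ecotype and the pete1 pete2 double mutant, both grown on MS medium, a standard mineral medium for plant culture. The mutant lacks both isoforms of plastocyanin, the copper protein of the thylakoid lumen that carries electrons to photosystem I. Total RNA was measured on a one-colour array, and the table used here held 3439 features in 12 columns, 6 for each genotype. Of these features, 692 were assigned to 1 gene, 870 to several genes and 1877 were not listed in the annotation, so that 691 distinct genes could be named. The intensities of a column summed to between 3493 and 3778 relative units, and the column medians lay between 0.341 and 0.659. Between 170 and 264 features were listed at 0 in a column, and 95 features were listed at 0 in all 12 columns. The number of arrays limits the precision of every comparison.

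The 6 columns of each genotype fell into 3 pairs, numbers 1 and 2, 3 and 4, and 5 and 6. The median absolute log2 difference over features was between 0.0957 and 0.134 within these pairs. It was between 0.300 and 0.540 for other columns of the same genotype, and between 0.308 and 0.507 for columns of different genotypes. All 12 columns had their own partner as the nearest column. Each pair was therefore averaged and counted as 1 replicate, giving n = 3 per genotype.

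**Figure D1:**
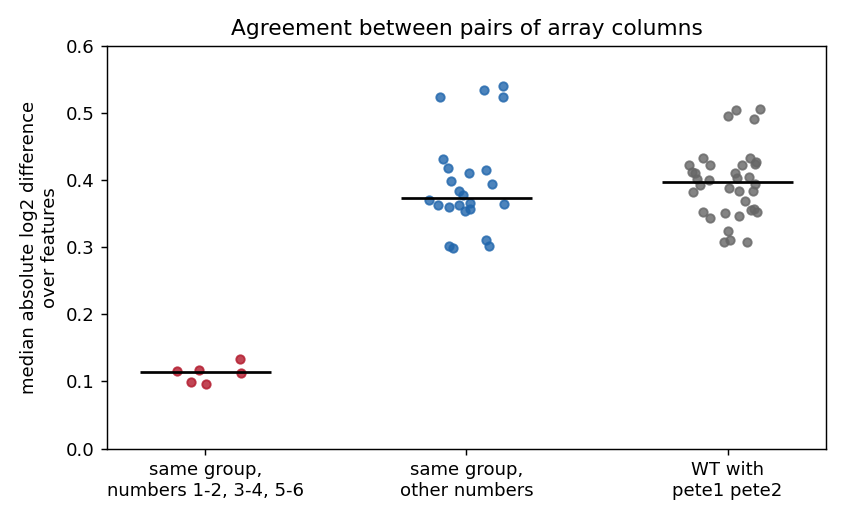
Median absolute log2 difference over all features (y axis) for every 2 columns, each point being a comparison of 2 columns and the horizontal line the median of its kind. The 6 comparisons within numbers 1 and 2, 3 and 4, or 5 and 6 lie between 0.0957 and 0.134, below all others, of which the lowest is 0.300.

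The comparison asks which nuclear transcripts differ when plastocyanin is missing. Feature 975, which has no gene name here, rose in pete1 pete2 from a normalised intensity of 1.19 ± 0.134 to 9.002 ± 0.764 (SD, n = 3), a log2 fold change of 2.92 (SE 0.12), with all 3 mutant pairs above all 3 WT pairs. No named gene passed the test in either direction. The named genes with the smallest p among those higher in the mutant were led by AT3G09080, with a log2 fold change of 1.24 (SE 0.18), and AT1G78620 (VTE6), the phytyl phosphate kinase of tocopherol synthesis, with 0.69 (SE 0.12). Among those lower, they were led by AT1G68660 (CLPS1), an adaptor of the plastid Clp protease, with a log2 fold change of -0.53 (SE 0.08). Of the 23 measured genes from 25 lists of plastid functions, none passed, including the measured subunits of both photosystems and the measured Calvin cycle enzymes.

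With limma and Benjamini-Hochberg adjustment at 0.05, 1 of 3438 tested features was higher in the mutant, feature 975 (adjusted p = 0.00908), and 0 were lower. At an unadjusted p under 0.05, 159 were higher and 92 lower, 251 in all, where independent features without any difference give 171.9. More features than these 251, from 286 to 483, reached that level in 3 of the 9 other splits of the 6 pairs into 3 and 3. All 3 mutant values lay above, or all 3 below, all 3 WT values for 341 features, or 9.92%, where chance gives 10%. Counting the 12 columns as separate samples, as planned beforehand, gave 149 higher and 75 lower features, 40 of them named genes. That fit takes the closely agreeing columns of a pair as independent, so its p-values can be too small. Keeping the duplicate pairs as a random block in the same limma model gave 15 higher and 4 lower. The random block uses 1 within-pair correlation for all features. Its residual degrees of freedom come from the 12 columns, so its p-values can be too small as well. The log2 fold change of feature 975 stayed between 2.75 and 3.12 in every alternative. Its call was lost with the values as deposited, with median centring, with scaling to the total, and without any 1 of 5 of the 6 pairs. Over these scalings and omissions the limma adjusted p was from 0.0769 to 0.160. A block on the replicate number, a fit with fewer degrees of freedom, also lost the call (limma adjusted p = 0.630). Of the fits without a pair, the one without WT columns 3 and 4 kept it, at 0.0252.

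Plastocyanin itself is encoded by PETE1 and PETE2, the genes disrupted in the mutant. 0 features were assigned to either gene, alone or with others, so their transcripts could not be identified and the genotype labels have no check from them. Whether any of the 1877 tested features not listed in the annotation measures either gene cannot be told here. Feature 1430, unnamed here, was the only feature listed at 0 in all 6 mutant columns and above 0 in all 6 WT columns, where its deposited intensity was between 0.114 and 0.412. It did not pass limma's test (adjusted p = 0.172), but did without WT columns 3 and 4 (0.0252) and after the correction for neighbouring features (0.00619). It passed in no other setting based on pair means, nor with the pairs as a random block. All its mutant values were raised to the floor, so their SD of 0 is set by the floor. 0 features were listed at 0 in all 6 WT columns and above 0 in all 6 mutant columns. Feature 3502, which is assigned to several genes, was listed at 0 in 4 of the 6 mutant columns, did not exceed 0.0659 in the others and lay between 0.207 and 0.634 in WT. Its limma adjusted p was 0.0782, and it passed with median centring (0.0214), with array weights (0.0316), without WT column 4 (0.0458), 6 (0.0379) or the pair 1 and 2 (0.0222), after the correction for neighbouring features (0.0051) and with the pairs as a random block (0.0103). No other setting based on pair means brought it past the threshold. Feature 3149, also assigned to several genes, had a normalised intensity of 0.533 ± 0.0951 in WT and 1.76 ± 0.150 in the mutant (SD, n = 3), with a log2 fold change of 1.74 (SE 0.17) and a limma adjusted p of 0.172. It passed with the pairs as a random block (adjusted p = 0.00391) and without the dimmest 50% of features (0.0378). All 3 of these features passed when the 12 columns were counted as separate samples, with or without a block on the replicate number. Both of those fits take the columns of a pair as independent.

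The 10 named genes with the smallest p, 5 in each direction, did not pass, and the smallest limma adjusted p of any named gene was 0.327, that of AT3G09080. The normalised intensity of AT3G09080 was 1.91 ± 0.391 in WT and 4.46 ± 0.322 in the mutant (SD, n = 3). AT1G62250 was among the brighter of them, at 4.66 ± 0.323 in WT and 7.56 ± 1.198 in the mutant, with a log2 fold change of 0.69 (SE 0.15). AT1G78620 (VTE6) measured 0.539 ± 0.0141 and 0.873 ± 0.122. AT4G00170 had a log2 fold change of 0.71 (SE 0.13) and AT3G26580 one of 0.51 (SE 0.12). On the lower side, AT1G68660 (CLPS1) measured 0.929 ± 0.05001 in WT and 0.644 ± 0.0181 in the mutant. AT5G53920 had a log2 fold change of -0.65 (SE 0.11), and DI21, named as a drought-induced gene, one of -0.67 (SE 0.16). AT4G05490 had a log2 fold change of -0.37 (SE 0.09) and AT1G32220 one of -0.92 (SE 0.25). All 10 genes passed when the 12 columns were counted as separate samples, a fit that takes the columns of a pair as independent. Only AT3G09080 among them passed with the duplicate pairs as a random block (limma adjusted p = 0.00156), where p-values can be too small. The other named gene to pass there was AT4G27390, singled out after its values were seen, with a log2 fold change of 0.61 (adjusted p = 0.0425).

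**Figure D2:**
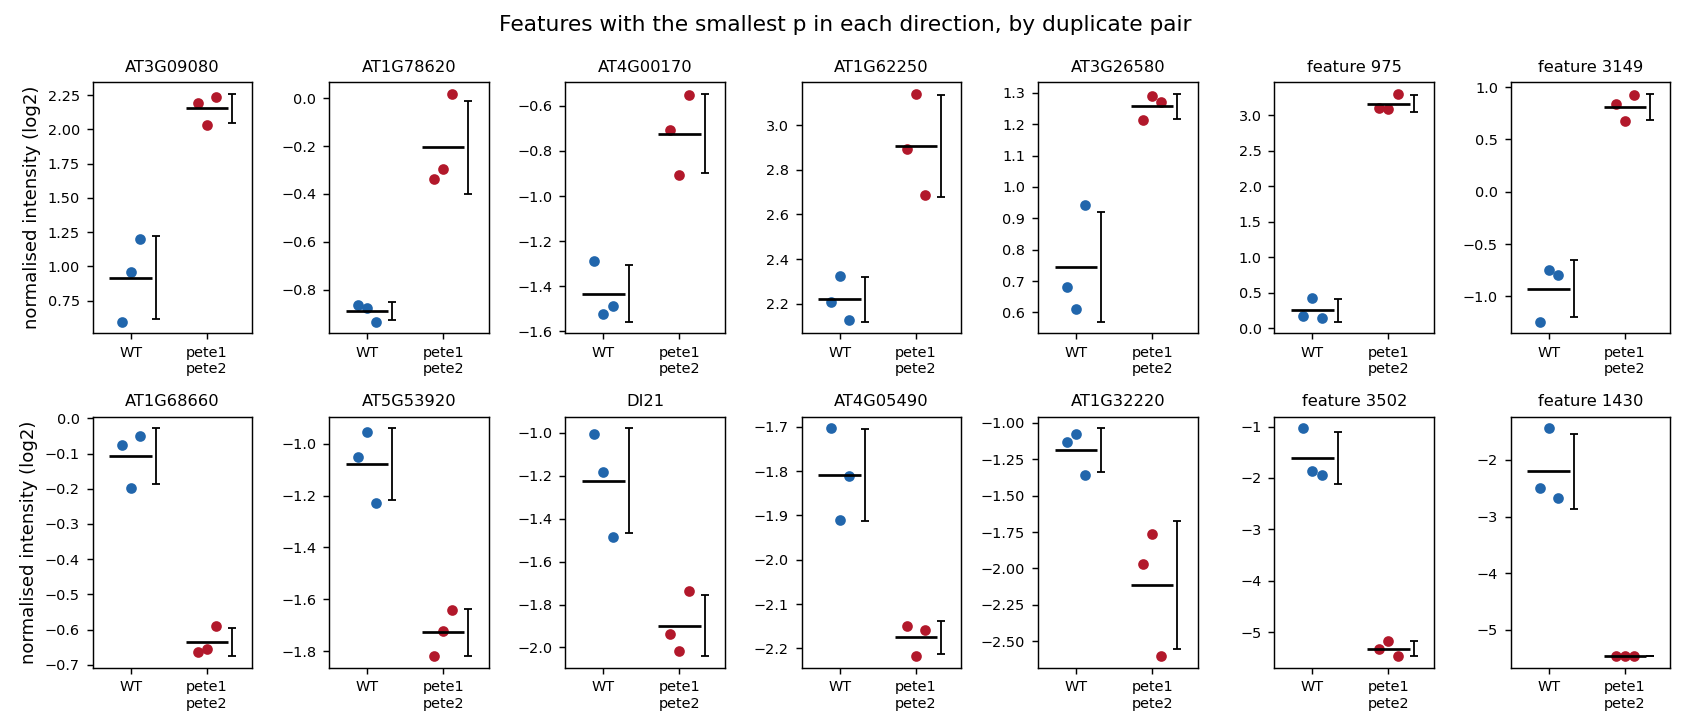
Normalised intensity on a log2 scale (y axis, with its own range in each panel) of the 10 named genes and 4 features without a single gene name, WT in blue and pete1 pete2 in red. Points are the 3 duplicate pairs, horizontal lines the group means and bars the SD; only feature 975 passed the test, and the 3 mutant points of feature 1430 lie at the floor given to values of 0.

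Among genes of the light reactions, 3 photosystem II proteins, 1 photosystem I protein, 1 antenna protein and 1 subunit of the NADH dehydrogenase-like complex were measured, and none passed. PSBW, a small membrane subunit of photosystem II, was the brightest, at 32.4 ± 12.7 in WT and 44.1 ± 14.6 in the mutant (SD, n = 3), with a log2 fold change of 0.46 (SE 0.38). PSB27, an assembly factor of photosystem II, had a log2 fold change of -0.62 (SE 0.37), and PSBY, another subunit, one of -0.24 (SE 0.24). PSAN, a lumenal subunit of photosystem I, measured 2.47 ± 0.405 in WT and 2.67 ± 0.363 in the mutant, a log2 fold change of 0.12 (SE 0.17). LHB1B2, an antenna protein of photosystem II with near-identical relatives that an array may not separate, had a log2 fold change of -0.23 (SE 0.32), which became 0.21 when each array was centred on its median. NdhN had one of -0.13 (SE 0.64). In the Calvin cycle, SBPASE, the sedoheptulose bisphosphatase, had a log2 fold change of -0.46 (SE 0.18), and PRK, the phosphoribulokinase, one of 0.07 (SE 0.35), which was -0.14 with the values as deposited and -0.12 with scaling to the total. When 1 column or pair was left out, the log2 fold change of SBPASE ranged from -0.70 (without mutant column 4) to -0.25 (without mutant column 3), that of PSBW from 0.21 to 0.77, that of PSB27 from -0.87 to -0.31 and that of PSBY from -0.36 to -0.029, while PSAN, LHB1B2, NdhN and PRK changed sign. Pooled into a list after the data were seen, these 8 genes had a mean log2 fold change of -0.13 and a median of -0.18, and a mean of 0.093 when each array was centred on its median and from -0.27 to -0.044 when 1 column or pair was left out. Limma's camera test did not separate the pooled list from other genes (adjusted p = 0.909, and adjusted p = 0.930 with an estimated correlation).

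Plastid ribosomal proteins were the only list fixed beforehand with at least 4 measured members. Of its 6 measured members, 4 had positive and 1 a negative log2 fold change, 1 was listed at 0 in all columns, and 0 passed over all features or adjusted over the list alone. AT3G13120 (PRPS10) had a log2 fold change of 0.72 (SE 0.40), AT1G64510 (PRPS6) one of 0.50 (SE 0.51), AT3G54210 (PRPL17) one of 0.25 (SE 0.16) and AT1G29070 (PRPL34) one of -0.71 (SE 0.59). That of AT1G29070 was -1.31 without mutant column 1 and -0.099 without mutant column 2. AT4G01310 (PRPL5) had one of 0.13 (SE 0.38), which was -0.14 with the values as deposited and -0.12 with scaling to the total. When 1 column or pair was left out, that of AT1G64510 ranged from 0.049 to 0.82, that of AT3G13120 from 0.42 to 1.09, that of AT3G54210 from 0.11 to 0.40 and that of AT4G01310 from -0.25 to 0.34. AT5G65220 (PRPL29) was the member listed at 0. The mean over the list was 0.15 and the median 0.19. The mean ranged from 0.044 (without mutant column 1) to 0.28 (without mutant columns 3 and 4) when 1 column or pair was left out, and was -0.046 with the values as deposited and -0.035 with scaling to the total, and camera gave an adjusted p of 0.909 (adjusted p = 0.930 with an estimated correlation).

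The other measured members of the fixed lists did not pass either. FATB, the acyl-ACP thioesterase of plastid fatty acid synthesis, was the only one of the 23 with an unadjusted p under 0.05, at 0.124 ± 0.0464 in WT and 0.289 ± 0.101 in the mutant (SD, n = 3), with a log2 fold change of 1.22 (SE 0.39) and a limma adjusted p of 0.583. It passed when the 12 columns were counted as separate samples (limma adjusted p = 0.0254), but not with a block on the replicate number added to that fit or with the duplicate pairs as a random block. Its log2 fold change was between 0.94 and 1.55 when 1 column or pair was left out. AT1G24360 (FABG), of the same pathway, had a log2 fold change of -0.13 (SE 0.17). For chlorophyll synthesis, CHLM, the magnesium protoporphyrin methyltransferase, had one of -0.11 (SE 0.30), and AT1G74470 (CHLP), the geranylgeranyl reductase, one of -0.02 (SE 0.15), which became 0.22 when each array was centred on its median. Of the redox enzymes, AT3G52960 (PRXIIE), a peroxiredoxin, had a log2 fold change of -0.34 (SE 0.25), NTRC, an NADPH-dependent thioredoxin reductase, one of -0.19 (SE 0.31), and AT2G04700 (FTRB), of the ferredoxin-thioredoxin reductase, one of 0.23 (SE 0.44), which was -0.0089 with the values as deposited. AT5G17630 (XPT), a sugar phosphate transporter of the envelope, had one of -0.28 (SE 0.25), and APS4, an ATP sulfurylase, one of -0.21 (SE 0.32). When 1 column or pair was left out, AT1G24360 ranged from -0.26 to -0.016, AT3G52960 from -0.54 to -0.20 and AT5G17630 from -0.49 to -0.14, while CHLM, AT1G74470, NTRC, AT2G04700 and APS4 changed sign. The list of markers for root plastids had 0 measured members, so the share of non-green tissue was not analysed here.

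The balance of higher against lower features followed the scaling between arrays. Among features with an unadjusted p under 0.05 in limma, 63.3% were higher in the mutant after quantile normalization and 73.9% with median centring, against 32.9% with the values as deposited and 33.3% with scaling to the total. The median log2 fold change of all features was -0.01 after quantile normalization, -0.27 as deposited and -0.26 with scaling to the total.

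Features with neighbouring numbers differed together between arrays of 1 genotype. Across features, which are not independent replicates, the log2 difference between WT pairs correlated between features 1 apart with Pearson's r of 0.48, 0.37 and 0.31 for the 3 comparisons of WT pairs. Between features 288 apart r was 0.40, 0.31 and 0.20. The 3 comparisons of mutant pairs gave 0.13, 0.24 and 0.094 at a distance of 1, and 0.13, 0.16 and 0.12 at 288. The difference between the genotypes had an r of 0.16 at a distance of 1 and 0.12 at 288.

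**Figure D3:**
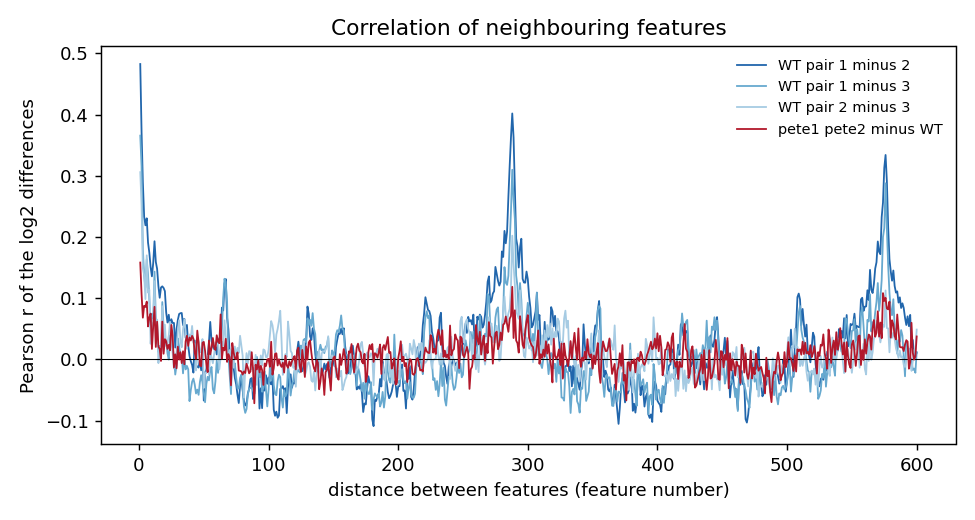
Pearson's r of log2 differences between features (y axis) against their distance in feature number (x axis), with the 3 comparisons of WT pairs in blue and the genotype difference in red. The blue lines reach 0.48, 0.37 and 0.31 at a distance of 1 and rise again to 0.40, 0.31 and 0.20 at 288, while the red line is at 0.16 and 0.12.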

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

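The 12 columns as separate samples were the planned analysis, and the pair means were made the main one after the data were seen. Also chosen then were the random block, the block on 12 columns, the correction for neighbours and the omission of whole pairs. Signal over background limits dim features, as the background was not given in the sources used here. Unless a value below shows it, the cause was not tested. No named gene passed limma's test (Benjamini-Hochberg) under any alternative that used pair means, and no list passed under any. Over 1096 values of single genes and features under the alternatives, 1011 kept their direction and side of the threshold, 39 passed where the main value did not, 9 lost a call and 37 changed sign. Of 218 list values, 187 kept both and 31 changed sign. Of the 39, 14 came from the 12 columns as separate samples, 13 from the block on 12 columns and 3 from the random block. The trended variance, the replicate block and the 12 columns leave each log2 fold change as it was, so direction could not change there. The near-copies of LHCB1 and RBCS, the PETE genes and quantile normalization as an alternative gave no separate result.

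With the values as deposited, 0 features were higher and 32.9% of those with an unadjusted p under 0.05 were higher. The log2 fold changes were -0.14 for PRK, -0.14 for AT4G01310 and -0.0089 for AT2G04700. The list means were -0.24 for pigment synthesis, -0.32 for glycosyl hydrolases, -0.18 for histone H3 and kinesins, -0.12 for redox genes and -0.046 for plastid ribosomal proteins. With scaling to the total, 0 features were higher and 33.3% were higher at the unadjusted p, with -0.12 for PRK and -0.12 for AT4G01310. The list means were -0.23 for pigment synthesis, -0.30 for glycosyl hydrolases, -0.17 for histone H3 and kinesins, -0.099 for redox genes and -0.035 for plastid ribosomal proteins. Neither aligns the array medians, and the median over all features was -0.27 and -0.26. With median centring, 0 features were higher, 1 was lower (feature 3502) and 73.9% were higher at the unadjusted p, with 0.21 for LHB1B2 and 0.22 for AT1G74470. The list means were -0.049 for glycosyl hydrolases, 0.093 for the pooled photosynthesis genes and 0.027 for photosystem assembly and RNA factors.

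The mean of pigment synthesis, 0.00 in the main analysis, was -0.012 with a pseudocount and -0.11 without the dimmest 25% or the dimmest 50% of features. Without the dimmest 50%, 2 features were higher, 975 and 3149. There were fewer features to adjust over, and the variance estimate changed too. The SE of feature 3149 was 0.24 there and 0.17 in the main analysis. With array weights, whose estimate stopped before it converged, 1 feature was lower, and LHB1B2 had 0.099, AT1G74470 had 0.15 and APS4 had 0.022.

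The replicate numbers were not taken to pair the samples, since not every same-numbered correlation across features was over 0.1. The deviations of same-numbered pair means correlated with 0.32, 0.00 and 0.39, and those of same-numbered columns with 0.31, 0.33, 0.069, 0.068, 0.44 and 0.41. WT pairs 1 and 3 correlated best with the mutant pair of their own number and WT pair 2 did not. Deviations were taken from the mean of the 3 pairs of a genotype, so a low correlation for 1 pair cannot exclude a shared effect. Pairing by number therefore stays open. With the replicate number as a block, 0 features were higher and 0 lower, and feature 975 kept its log2 fold change of 2.92 with an SE of 0.15 and an adjusted p of 0.630 in limma. That fit has fewer degrees of freedom. With a block on the 12 columns, which takes the columns of a pair as independent, 156 features were higher and 93 lower.

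With the 12 columns as separate samples, 149 features were higher and 75 lower (224 in all). With the pair as a random block, at a within-pair correlation of 0.858, 15 were higher and 4 lower, all 19 among the 224. Both of these fits can give p-values that are too small, for the reasons given in the report. After the correction for neighbouring features, 1 was higher and 2 were lower. It gave -0.14 for PRK, 0.21 for CHLM, -0.014 for AT4G01310, 0.029 for AT1G24360 and -0.047 for glycosyl hydrolases. The correction was tried with 4 window sizes, and each gave the same 3 features.

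When 1 column or 1 pair was left out, between 0 and 1 features were higher and between 0 and 1 lower. The share higher at the unadjusted p was between 49.6% (without mutant columns 5 and 6) and 66.5%. Log2 fold changes ranged from -0.017 to 0.23 for PSAN, -0.47 to 0.0014 for LHB1B2, -0.72 to 0.16 for NdhN, -0.17 to 0.37 for PRK, -0.40 to 0.12 for CHLM, -0.14 to 0.074 for AT1G74470, -0.25 to 0.34 for AT4G01310, -0.45 to 0.037 for NTRC, -0.084 to 0.56 for AT2G04700 and -0.44 to 0.058 for APS4. List means ranged from -0.10 to 0.11 for pigment synthesis, -0.18 to 0.22 for glycosyl hydrolases, -0.11 to 0.0090 for photosystem assembly and RNA factors, 0.044 to 0.28 for plastid ribosomal proteins and -0.27 to -0.044 for the pooled photosynthesis genes.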

Other observations

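Every test of an explanation in this part, and every list in its first paragraph, was chosen after the data had been seen. Of 7 genes for redox functions of the plastid, 4 had positive and 3 negative log2 fold changes and none passed limma's test. The largest was that of AT3G47860 (CHL), the chloroplastic lipocalin, at 0.67 (SE 0.27). Of 5 genes of chlorophyll, siroheme and carotenoid synthesis, Z-ISO, the zeta-carotene isomerase, had -0.64 (SE 0.34) and HEMA3, a glutamyl-tRNA reductase, 0.33 (SE 0.18). Of 10 factors for photosystem assembly, the NDH complex and plastid RNA, 3 were positive, 6 negative and 1 listed at 0 in all columns. NDHS, the brightest of them at 8.27 ± 0.623 in WT and 7.496 ± 0.465 in the mutant (SD, n = 3), had -0.14 (SE 0.10). Of 7 genes for histone H3 and kinesins, 3 were positive, 3 negative and 1 listed at 0, and 4 glycosyl hydrolases of family 9B split into 2 positive and 2 negative. Limma's camera gave adjusted p of 0.909 for the redox genes, the assembly factors and the histone list, 0.910 for pigment synthesis and 0.973 for the glycosyl hydrolases.

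The 6 pairs can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 1 feature and the highest of the others 0, so 1 split gave as many. At an unadjusted p under 0.05 the real split had 251 features, fewer than 3 of the 9 other splits (286 to 483). The highest was WT pairs 1 and 3 with mutant pair 2 against the rest.

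Feature 975 differed between the genotypes by 2.92 on the log2 scale (SE 0.12). A regional deviation of the arrays is argued against by its 16 neighbours, whose median difference was -0.061 (from -1.11 to 0.39), and by its difference of 2.97 after correction for them (limma adjusted p = 0.0051). Scaling between arrays does not account for the size, which was at least 2.85 under the 3 other scalings, but the call was lost under each of them. The lowest adjusted p there was 0.0870 in limma, with an SE of 0.22 as deposited, 0.44 with median centring and 0.25 with scaling to the total. These exceed the SE of 0.12 after quantile normalization. Removing the dimmest features, at either share, kept the call with an SE of 0.222 (limma adjusted p = 0.00229 and 0.000561). The correction for neighbours kept it with an SE of 0.213. The larger SE alone therefore does not account for the loss with the values as deposited, and the cause of the loss was not tested. An effect of the genotype stays open, and the 10 splits are too few to decide on chance.

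Neighbouring features deviated together between pairs of 1 genotype, as given in the report. A candidate explanation is position on the array, with rows of 288 features. The distance of 288 was picked from the difference of WT pairs 1 and 2, so WT values at that distance are no test of it. In the comparisons of mutant pairs, whose arrays were not used for that choice, the lowest r at 288 was 0.12, against at most 0.0585 at 100 to 200 apart, which is consistent with position. The mean signal over all pairs had an r of 0.00 at a distance of 1 and 0.14 at 288, so deviations that follow the level of features 1 row apart stay open, and no biological explanation was tested. Correction for neighbours left feature 975 past the threshold and added features 3502 and 1430, both lower in the mutant (limma adjusted p = 0.0051 and 0.00619), where 1430 is listed at 0 in all 6 columns and 3502 in 4 of them.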
